A study of Rattus norvegicus with 9 samples.

How the data were processed

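Total RNA from 9 rat cell samples was labelled as biotinylated cRNA and hybridised to Affymetrix whole-genome rat expression arrays. The deposited table holds 31099 probe sets on 9 arrays, with no missing values. Its values are on a log2 scale and were made by the authors with RMA in Partek, per the submitters' processing notes, which state no versions. RMA subtracts background, equalises the distribution of intensities between arrays and summarises the probes of each probe set. The values fit that description, since they ran from 2.38 to 13.8 and every array had nearly the same mean. Equalised distributions remove any difference in total RNA content between cell types, so a higher or lower value is relative to the other genes of the same array. RMA also compresses differences near background, so large folds are approximate. No detection calls were used. The number of arrays limits the precision.

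Probe sets were assigned to genes with the array annotation. Of all probe sets, 57 were controls, 20832 had 1 gene symbol, 436 had several and 9831 had none. Probe sets with exactly 1 gene symbol were kept. The probe set with the highest mean over the 9 arrays stood for its gene, which gave 14217 genes, 4525 of them with more than 1 probe set. A reference table of rat genes was used for gene names only.

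Arrays were grouped by their labels into fibroblasts (2 arrays), acutely isolated OPCs (1 array), iOPCs (2 arrays) and primary cells at day 3 (2 arrays) and day 6 (2 arrays) of differentiation. The replicate numbers of the labels were not used as pairs. The 7 comparisons were made with limma 3.58.1 in R 4.3.3. Linear models with group means were fitted over all 9 arrays, with 4 residual and 4 prior degrees of freedom, and tested with moderated, 2-sided limma statistics. P-values were adjusted by the Benjamini-Hochberg method over all genes within a comparison, and a gene was said to rise, fall or change at an adjusted p below 0.05. The acutely isolated OPCs were assumed to vary like the other groups. The replicated groups did not vary alike, with a median SD of 0.117 in fibroblasts, 0.125 in iOPCs, 0.067 at day 3 and 0.06 at day 6. The shared spread is thus wide for day 3 and day 6 and narrow for fibroblasts and iOPCs. This bears on p-values and on fits of only the groups compared. The p-values reflect the spread between these arrays and not the spread between animals or laboratories.

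The comparisons, the tests, 17 gene lists and the rule for naming genes were chosen before the data were examined. The lists covered myelin and mature oligodendrocytes, committed oligodendrocyte precursors, oligodendrocyte precursors, fibroblasts and mesenchyme, the cell cycle, cholesterol synthesis, neurons, astrocytes, microglia and macrophages, endothelial and mural cells, Schwann cells and neural crest, melanocytes, the interferon response, immediate early genes, senescence and the p53 response, the Hox cluster and forebrain patterning. Fabp7, Thy1, S100b and Egr2 each stood in 2 lists. Each list was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 17 lists of a comparison, and its members were counted over all genes and adjusted over the list alone. Over the 119 list tests, 71 passed with camera at the preset correlation and 7 of these also with an estimated correlation. With an estimated correlation, camera also refers its statistic to the 4 residual degrees of freedom. For the Schwann cell list of iOPCs against fibroblasts the estimated correlation was -0.01, yet the unadjusted camera p went from 4.1e-11 to 0.0019. A call lost in this version is thus not by itself a sign of correlated members. Limma's fry, which tests a list without setting it against other genes, was also planned and run. Its results are given only for lists of iOPCs against fibroblasts where the reading differs. A separate set of reference genes served for rescaling, of which 7 were measured.

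Named genes were the 8 largest rises and 8 largest falls of a comparison among genes that passed the test and whose arrays did not overlap, up to 4 changed members of each list by size of change, and a set of core genes of which 16 were measured. The core genes were Sox10, Olig2, Zfp536, Olig1, Pdgfra, Cspg4, Mbp, Mag, Mog, Cnp, Myrf, Col1a1, Col1a2, Fn1, Twist1 and Mki67. Similarity was the Pearson correlation across genes, with no test.

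The fits were tested on simulated data with 200 changed genes in each of 10 sets. A 2-fold change was recovered for 91.7% of genes in the comparison of iOPCs with fibroblasts, and for 75.9% to 77.8% in comparisons with the single OPC array. A 1.41-fold change was recovered for 3.6% to 19.3%. Between 5.9 and 8.5 unchanged genes were called per set. In these sets each gene had the same spread in every group, and few genes changed. In the real comparisons 32.3% to 55.8% of genes changed, and the groups differed in spread. The recovery rates and the numbers of false calls therefore do not carry over to the real comparisons. Alternatives covered quantile normalisation, rescaling on reference genes, a filter on dim genes, the mean of all probe sets, another variance model, a 2-fold minimum, fits of only the groups compared, a block for the replicate number and leaving out each replicated array. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.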

Results

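Expression was measured in 5 groups of Sprague-Dawley rat cells. Fibroblasts (2 arrays) were embryonic cells grown in serum and passaged 3 times. Oligodendrocyte precursor cells (OPCs, 1 array) were immunopanned from neonatal cortex and lysed directly. Induced OPCs (iOPCs, 2 arrays) were cells panned with the O4 antibody, a marker of the oligodendrocyte lineage, 3 weeks after infection. In the study, as known from outside the labels, fibroblasts received Sox10, Olig2 and Zfp536. Primary OPCs that had been expanded in mitogens and then given differentiation medium with thyroid hormone were taken at day 3 (2 arrays) and day 6 (2 arrays). Replicate arrays had Pearson correlations across genes of 0.989 (fibroblasts), 0.99 (iOPCs), 0.998 (day 3) and 0.998 (day 6). The acutely isolated OPCs had no replicate, so their values carry no SD.

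The first principal component held 57.1% of the variance and set the fibroblasts (115.9 and 114.8) apart from the primary oligodendroglial cells (-59.0 to -50.2), with the iOPCs between them (25.7 and 25). The second held 19.4% and placed the iOPCs (-57.6 and -58.2) and the acutely isolated OPCs (75.1) at opposite ends.

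**Figure D1:**
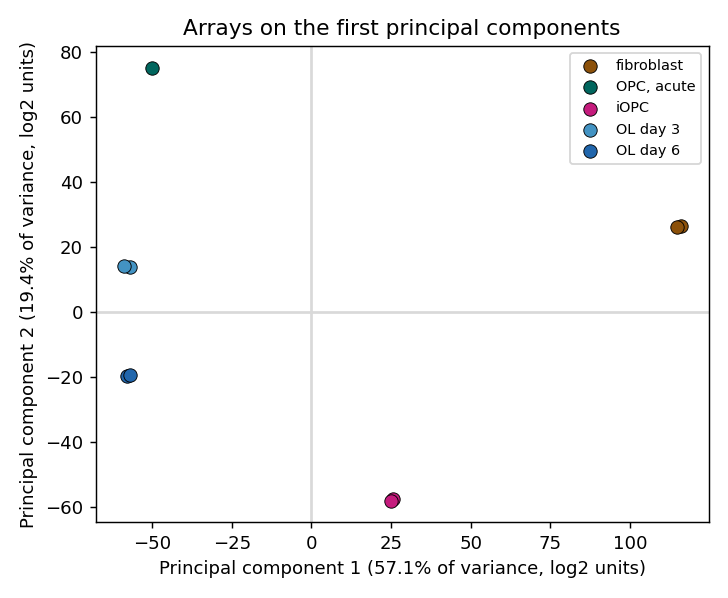
Each point is 1 array placed by its first (x axis) and second (y axis) principal component over all genes, in log2 units, and coloured by group. The iOPC arrays lie at 25.7 and 25 on the first component, between the fibroblasts (115.9 and 114.8) and the primary cells.

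The comparison of iOPCs with fibroblasts asks what changed in the cells that were converted. Genes of myelin were among the largest rises. Enpp2 (autotaxin, a lysophospholipase of oligodendrocytes) rose 487-fold, from 3.86 ± 0.07 to 12.79 ± 0.24 (SD, n = 2 arrays per group), and Apod (an apolipoprotein of myelinating glia) rose 484-fold. Mbp (myelin basic protein) rose 294-fold to 12.72 ± 0.11, Mag (a myelin adhesion glycoprotein) 252-fold and Cldn11 (the tight junction protein of myelin) 251-fold. The pigment gene Dct (379-fold), Pnlip (a lipase of the pancreas, 283-fold) and Bcas1 were also among the 8 largest. Myrf, a transcription factor that drives myelin genes, rose by 5.74 on the log2 scale, Mog by 4.79 and Cnp by 4.75. Mobp, another myelin protein gene, stood at 4.07 in fibroblasts and 4.18 in iOPCs. Of 33 myelin genes 26 rose and 3 fell (camera adjusted p = 1.2e-11; adjusted p = 0.12 with an estimated correlation). Of 16 genes of committed precursors 14 rose and 1 fell, among them Bcas1 (262-fold), Zfp488 (6.29) and Nkx2-2 (4.73) (adjusted p = 1.2e-08; adjusted p = 0.13 with an estimated correlation). Counts adjusted over the list alone were the same for both lists.

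Genes of the precursor stage were divided. Of 31 such genes 16 rose and 4 fell (17 and 4 adjusted over the list alone; adjusted p = 0.00019, and adjusted p = 0.22 with an estimated correlation). Ptprz1 (a receptor phosphatase of precursors) rose by 5.81, Sox6 by 4.77, Gpr37l1 by 4.29 and Mmp15 by 3.99. Pdgfra, the receptor for the precursor mitogen PDGF-AA, fell by 2.00 to 7.38 ± 0.85, and Cspg4 (the proteoglycan NG2) fell by 3.37 to 4.85 ± 0.17. Sox10 rose by 1.49 to 6.08 ± 0.15 and Zfp536 by 5.44 to 10.44 ± 0.11, and all 4 Zfp536 probe sets were higher in iOPCs. Olig1 stood at 3.93 ± 0.09 in fibroblasts and 4.22 ± 0.10 in iOPCs (adjusted p = 0.052). Olig2 rose by 2.85 to 7.31 ± 0.02 on the probe set used, while its other probe set stood at 4.08 in fibroblasts and 4.09 in iOPCs. Sox10, Olig2 and Zfp536 are the factors named above as delivered. Whether their probe sets read delivered copies, the cells' own genes or both was not tested. Sox10 and Olig2 also count among the rises of the precursor list.

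Genes of fibroblasts fell. Of 44 fibroblast and mesenchyme genes 37 fell and 2 rose (38 and 2 adjusted over the list alone; adjusted p = 7e-10, and adjusted p = 0.23 with an estimated correlation). Lox (which crosslinks collagen) fell by 6.54 ± 0.70 (SE), Tagln by 5.65 and Acta2 by 5.52, both contractile proteins, and Meox2 (a mesodermal homeobox factor) by 4.75. Col1a1 fell by 2.70 to 10.19 ± 0.21 and Col1a2 by 2.88 to 10.36 ± 0.86, while another collagen gene, Col6a3, rose by 2.44 to 7.52 ± 1.58. Fn1 (fibronectin) fell by 1.77 to 11.32 ± 0.08 and Twist1 by 2.11. The largest falls of all were in Prl8a9 (278-fold), Il1rl1 (212-fold), Itga11 (142-fold) and Tnnc1 (128-fold), followed by Ccn4, Prss35, Wfdc1 and Cnn1 (106-fold to 97.6-fold).

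Genes of peripheral glia and pigment cells rose too. Of 21 Schwann cell and neural crest genes 20 rose and 1 fell (adjusted p = 3.5e-10), and this call held with an estimated correlation (adjusted p = 0.033). Sox2 rose by 7.37, Scn7a (a sodium channel of Schwann cells) by 6.32, S100b by 6.20 and Ngfr (the p75 neurotrophin receptor) by 5.70. S100b is in the astrocyte list as well, so it does not mark peripheral glia alone. Of 10 melanocyte genes 5 rose and 1 fell (adjusted p = 0.01; adjusted p = 0.23 with an estimated correlation), led by Dct (379-fold), Pmel (7.43) and Tyrp1 (7.06), which act in pigment synthesis and pigment granules. Primary cells also held some of these, Pmel at 11.83 in acutely isolated OPCs and Dct at 10.32 at day 6. Of 23 immediate early genes 15 rose and 4 fell (adjusted p = 0.00012; adjusted p = 0.091 with an estimated correlation), with Fosb up by 5.99 and Fos by 4.85. Of 34 cell cycle genes 22 rose and 1 fell (23 and 1 adjusted over the list alone; adjusted p = 5.1e-06, and adjusted p = 0.46 with an estimated correlation), Mki67 by 2.07 ± 0.25 (SE). For the other lists of this paragraph the counts adjusted over the list alone were the same.

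Of 22 microglia and macrophage genes 14 fell and 0 rose (15 and 0 adjusted over the list alone; adjusted p = 0.0056, and adjusted p = 0.56 with an estimated correlation), among them C1qa by 2.49 and Ctss by 2.39. Fewer members of this list fell by the test when iOPC replicate 1 was left out. Of 27 interferon response genes 10 rose and 4 fell (12 and 4 adjusted over the list alone; adjusted p = 0.036, and adjusted p = 0.23 with an estimated correlation), with Psmb9 up by 2.00 and Ifit2 down (it fell by 2.58). The remaining lists did not pass with camera. With fry, the neuronal (adjusted p = 0.00022), Hox (0.0018), astrocyte (0.0026), cholesterol (0.037) and endothelial (0.038) lists did pass. The senescence (0.38) and forebrain (0.58) lists did not pass with fry, nor did the microglia list (0.056). The adjusted p-values that follow are from camera. Of 22 Hox genes, which encode body position, 10 fell and 3 rose (adjusted p = 0.17), and with only these groups fitted, a setting added after the data were seen, 6 fell. Of 19 senescence and p53 genes 11 fell and 3 rose (adjusted p = 0.075), of 20 cholesterol synthesis genes 10 fell and 4 rose (adjusted p = 0.17), and of 18 endothelial and mural genes 6 fell and 2 rose (adjusted p = 0.17). Neuronal genes were divided, with 9 up and 10 down of 28 (adjusted p = 0.5), as were those of astrocytes, with 7 up and 5 down of 21 (adjusted p = 0.46). Of 12 forebrain patterning genes 2 rose and 3 fell (adjusted p = 0.99), the falls being 5 without fibroblast replicate 1 and 1 with only these groups fitted. Counts adjusted over the list alone were the same for these lists.

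In all, 7189 of 14217 genes changed, 3329 up and 3860 down, and 2990 of them changed at least 2-fold. No list median of this comparison changed sign under either rescaling.

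**Figure D2:**
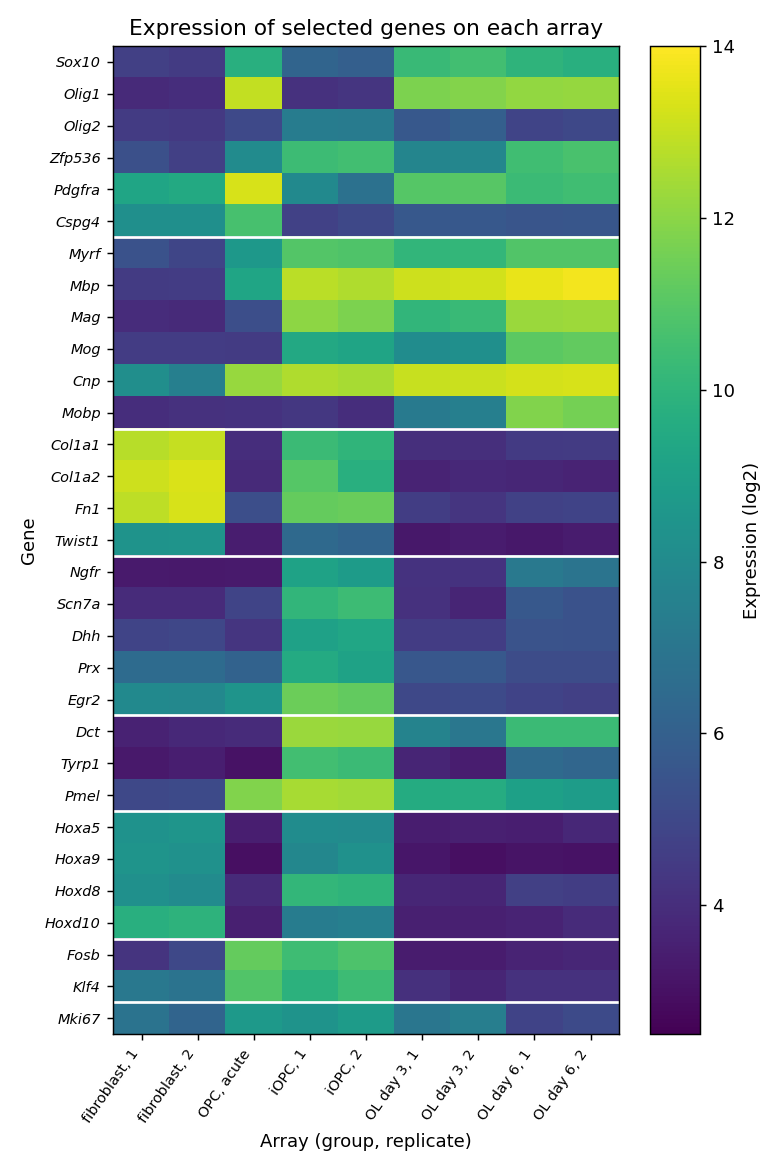
Colour gives the log2 expression of each gene (y axis) on each of the 9 arrays (x axis, group and replicate), with white lines between groups of genes, some of which were picked for display after their values were seen. Mbp stood at 12.72 in iOPCs against 4.52 in fibroblasts, while Olig1 stood at 4.22 in iOPCs against 12.92 in acutely isolated OPCs.

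The comparison of acutely isolated OPCs with fibroblasts gives the primary counterpart. Precursor genes were far higher in OPCs. Fabp7 (a fatty acid binding protein of neural progenitors) was 786-fold higher at 12.95, Rlbp1 568-fold, Olig1 (a basic helix-loop-helix factor of the lineage) 510-fold at 12.92 and Ptprz1 351-fold. Ttyh1, Bcas1, Scg3 and Gpm6a were 391-fold, 386-fold, 282-fold and 255-fold higher. The largest falls included matrix genes, with Postn 934-fold, Ccn2 843-fold, Col3a1 741-fold, Col1a2 655-fold and Lox 570-fold below the fibroblasts. Tpm2, Il1rl1 and S100a11 were between 584-fold and 535-fold lower.

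Of 31 precursor genes 30 rose and 0 fell in OPCs (adjusted p = 5.8e-16), and of 21 astrocyte genes 17 rose and 3 fell (adjusted p = 3.2e-06), with Aqp4 up by 7.19 and Gfap by 4.98. Both calls held with an estimated correlation (adjusted p = 0.048 for each). The fibroblast list had 39 falls and 0 rises (adjusted p = 1.4e-13; adjusted p = 0.2 with an estimated correlation), and the myelin list 21 rises and 4 falls (adjusted p = 2.7e-05; adjusted p = 0.2 with an estimated correlation). Committed precursor genes had 10 rises and 4 falls (adjusted p = 0.011; adjusted p = 0.28 with an estimated correlation). Cell cycle genes had 31 rises and 1 fall (adjusted p = 1.3e-08; adjusted p = 0.28 with an estimated correlation), and cholesterol genes 16 and 1 (adjusted p = 4.5e-05; adjusted p = 0.28 with an estimated correlation). Senescence and p53 genes had 14 falls and 4 rises (adjusted p = 0.0074; adjusted p = 0.26 with an estimated correlation), led by Cdkn2a, which encodes cell cycle inhibitors and fell by 7.82. Hox genes had 10 falls and 0 rises (adjusted p = 0.00041; adjusted p = 0.17 with an estimated correlation), though the list median of -0.41 became 0.09 when the arrays were rescaled on reference genes. All of these counts were the same adjusted over the list alone.

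Neuronal genes had 15 rises and 8 falls in OPCs (adjusted p = 0.02; adjusted p = 0.17 with an estimated correlation), with Gap43, a growth cone protein, up by 7.21. Immediate early genes had 14 rises and 4 falls (14 and 5 adjusted over the list alone; adjusted p = 0.02, and adjusted p = 0.17 with an estimated correlation). Microglia and macrophage genes had 12 falls and 1 rise, the same adjusted over the list alone (adjusted p = 0.038; adjusted p = 0.66 with an estimated correlation), but 1 fall with only these groups fitted. Schwann cell genes had 9 rises and 4 falls (adjusted p = 0.11), and forebrain patterning genes 5 and 2 (adjusted p = 0.12), the same adjusted over the list alone.

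Of all genes 7940 changed, 3752 up and 4188 down, so 47.3% were up, and 4597 changed at least 2-fold. Rescaling on reference genes moved the median of all genes from -0.071 to 0.431 and the share up to 74.5%. It moved the list medians of microglia genes from -1.26 to -0.75, of neuronal genes from 0.94 to 1.45 and of immediate early genes from 0.74 to 1.24.

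Calls against fibroblasts were then compared between iOPCs and OPCs. The same direction was found for 4445 genes (1954 up and 2491 down) and opposite directions for 762, of which 415 were up in iOPCs and down in OPCs. Independent calls would share 878.55 rises and 1137.1 falls. Both comparisons use the same fibroblast arrays, which are too few to divide, and 100 simulations of unchanged groups gave a mean of 0.04 shared calls. The simulations cover only noise in the shared arrays, since no simulated group differed from fibroblasts. Neither reference accounts for changes away from fibroblasts that are not particular to OPCs. The overlap therefore does not measure how far iOPCs resemble OPCs. The fold changes had a Pearson correlation across genes of 0.599 (simulated 0.407) and a covariance of 1.13 (simulated 0.0128). Of 2221 genes at least 2-fold higher in OPCs than in fibroblasts, 1316 (59.3%) rose in iOPCs and 202 fell, and of 2376 at least 2-fold lower, 1655 (69.7%) fell and 211 rose. Of 290 genes at least 16-fold higher in OPCs than in fibroblasts, 179 (61.7%) rose in iOPCs, 16 fell and 95 did not change by the test. Of 298 genes at least 16-fold lower, 267 (89.6%) fell in iOPCs, 6 rose and 25 did not change by the test. Of all 14217 genes, 3329 rose and 3860 fell in iOPCs against fibroblasts. Directly against OPCs, 1630 of the 2221 genes and 244 of the 290 were lower in iOPCs. Likewise, 1641 of the 2376 genes and 234 of the 298 were higher in iOPCs than in OPCs. These sets were chosen by their values on the single OPC array, which favours such differences.

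The direct comparison of iOPCs with acutely isolated OPCs asks how the induced cells differ from the primary precursor. Precursor genes were lower in iOPCs. Olig1 was 415-fold lower at 4.22 ± 0.10 (SD, n = 2) against 12.92, Rlbp1 250-fold and Cspg5 (a proteoglycan of neural precursors) 161-fold. Kcnd2, Vcam1, Aqp4, Ntrk2 and Nap1l5 were 203-fold to 134-fold lower. The largest rises included genes of matrix and pigment, with Ccn2 (a matrix protein induced in fibroblasts) 419-fold, Dct 324-fold, Col3a1 265-fold and Tyrp1 168-fold above OPCs. Anxa2, S100a11, Anxa1 and Pnoc (the precursor of nociceptin) were 304-fold to 198-fold higher.

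Of 31 precursor genes 26 fell and 2 rose (27 and 2 adjusted over the list alone; adjusted p = 1.2e-12, and adjusted p = 0.073 with an estimated correlation). Pdgfra fell by 5.93, Cspg4 by 5.78 and Sox10 by 3.68. Olig2 was higher by 2.28 on the probe set used, but lower on its other probe set (4.09 against 6.48), and the mean of both gave a difference of -0.05. Astrocyte genes had 16 falls and 1 rise (18 and 1 adjusted over the list alone; adjusted p = 5.1e-08, and adjusted p = 0.055 with an estimated correlation), neuronal genes 16 and 6 (18 and 6 adjusted over the list alone; adjusted p = 0.00062, and adjusted p = 0.077 with an estimated correlation). Cholesterol genes had 17 falls and 1 rise (the same adjusted over the list alone; adjusted p = 1.1e-07, and adjusted p = 0.19 with an estimated correlation). Cell cycle genes had 20 falls and 1 rise (21 and 1 adjusted over the list alone; adjusted p = 7e-05, and adjusted p = 0.42 with an estimated correlation), while Mki67 itself stood at 8.63 against 8.70.

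Among lists that rose, the fibroblast list had 29 rises and 2 falls (adjusted p = 3.8e-08; adjusted p = 0.19 with an estimated correlation), Col1a1 up by 6.19 and Fn1 by 6.06. Myelin genes had 16 rises and 3 falls (16 and 4 adjusted over the list alone; adjusted p = 0.00066, and adjusted p = 0.19 with an estimated correlation), with Mag up by 6.61, Mal by 5.94 and Mog by 4.82. Committed precursor genes had 10 rises and 3 falls (11 and 3 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.3 with an estimated correlation). Schwann cell genes had 14 rises and 3 falls (adjusted p = 0.00092; adjusted p = 0.077 with an estimated correlation), with Ngfr up by 5.68 and Scn7a by 5.35. Melanocyte genes had 7 rises and 0 falls (7 and 1 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.19 with an estimated correlation), 4 rises with only these groups fitted. Senescence and p53 genes had 11 rises and 2 falls (12 and 2 adjusted over the list alone; adjusted p = 0.0038, and adjusted p = 0.19 with an estimated correlation), with Cdkn2a up by 4.77 and Cdkn1a by 4.23. Hox genes had 8 rises and 0 falls (adjusted p = 0.0027; adjusted p = 0.18 with an estimated correlation), though the list median of 0.23 became -0.25 under rescaling on reference genes, while Hoxd8 was up by 6.17 and Hoxa9 by 5.12. Adjusted over the list alone, the fibroblast, Schwann cell and Hox counts were the same. Immediate early genes were divided, with 9 rises and 7 falls, a median of -0.05 and a mean of 0.28, the same counts adjusted over the list alone (adjusted p = 0.55).

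Of all genes 6693 changed, 3496 up and 3197 down, so 52.2% were up, and 3598 changed at least 2-fold. Rescaling on reference genes moved the median of all genes from 0.01 to -0.471 and the share up to 21.3%. It lowered the list medians of myelin genes from 0.57 to 0.08, melanocyte genes from 0.61 to 0.13, committed precursor genes from 1.10 to 0.62, senescence genes from 1.13 to 0.65, immediate early genes from -0.05 to -0.53 and cell cycle genes from -0.59 to -1.07.

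Differentiating primary cells were then compared with acutely isolated OPCs, where culture and isolation go together with stage. At day 3, against acutely isolated OPCs, Mag was 30.1-fold and Cldn11 26.8-fold higher, Mbp rose by 3.89 to 13.16 ± 0.07 and Mog by 3.63. H19 (an imprinted noncoding RNA), Adamts4 (a protease of oligodendrocytes), Igsf11, Lgals3 and Kif21a were 51.5-fold to 27.8-fold higher. Eif2s3y, a gene of the Y chromosome, was 38.4-fold higher, but it was low on the single OPC array only (3.21 against 8.20 to 8.47 in the other groups). Cspg4 was 31.2-fold and Hes5 (a Notch effector) 32.9-fold lower. The immediate early gene Fosb was 238-fold and Klf4 127-fold lower, and Col5a3, Tmem255b, Tnfaip3 and Kazald1 were 40.4-fold to 30.2-fold lower.

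Of 23 immediate early genes 20 fell and 1 rose at day 3 (adjusted p = 2.6e-10), a call that held with an estimated correlation (adjusted p = 0.031). Myelin genes had 17 rises and 2 falls (adjusted p = 0.00021; adjusted p = 0.3 with an estimated correlation), and committed precursor genes 13 rises and 0 falls (adjusted p = 9.4e-07; adjusted p = 0.15 with an estimated correlation). Precursor genes had 20 falls and 3 rises (adjusted p = 1.9e-06; adjusted p = 0.13 with an estimated correlation), and cell cycle genes 31 falls and 0 rises (adjusted p = 4.9e-11; adjusted p = 0.3 with an estimated correlation). These counts were the same adjusted over the list alone. Neuronal genes had 16 falls and 3 rises (17 and 4 adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.1 with an estimated correlation). Astrocyte genes had 12 falls and 2 rises (14 and 3 adjusted over the list alone; adjusted p = 0.00053, and adjusted p = 0.1 with an estimated correlation), while Gfap rose by 2.49. In all 5919 genes changed, 3140 up and 2779 down, 2794 of them at least 2-fold. The changes of Sox10 (0.65) and Cnp (0.80) were not called without OL day 3 replicate 2 (adjusted p = 0.0871 and 0.114), nor that of Cnp without replicate 1 (adjusted p = 0.102).

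Between day 3 and day 6 most myelin genes rose. Mal (a membrane sorting protein) rose 31.6-fold to 8.97 ± 0.32 and Klk6 (a myelin-associated protease) 28.2-fold (SD, n = 2 per group), while Mobp rose by 4.33 to 11.69 ± 0.15 and Mog by 3.02. Serpinb1a, Gpx2, Trh, Kndc1, Pdk4 and Fgl2 rose 41.8-fold to 21.0-fold. Falls were smaller, Cnr1 (a cannabinoid receptor) 7.38-fold and Dpysl3, Sorbs2, Cks2, Bex1, Fhl2, Uchl1 and Gask1b 7.18-fold to 5.46-fold.

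Of 33 myelin genes 26 rose and 2 fell (27 and 2 adjusted over the list alone; adjusted p = 1.4e-12, and adjusted p = 0.16 with an estimated correlation). Of 34 cell cycle genes 33 fell, the same adjusted over the list alone (adjusted p = 5.1e-21; adjusted p = 0.31 with an estimated correlation). Precursor genes had 18 falls and 1 rise (19 and 2 adjusted over the list alone; adjusted p = 1.1e-05, and adjusted p = 0.21 with an estimated correlation), with 9 falls without OL day 3 replicate 2 and 11 without OL day 6 replicate 1. Astrocyte genes had 10 rises and 1 fall (11 and 2 adjusted over the list alone; adjusted p = 0.00034, and adjusted p = 0.16 with an estimated correlation). Committed precursor genes had 5 rises and 7 falls (6 and 8 adjusted over the list alone) with a median of -0.44 and a mean of 0.31, and did not pass (adjusted p = 0.75). In all 4593 genes changed, 2090 up and 2503 down, so 45.5% were up, and 1298 changed at least 2-fold. Leaving out single arrays gave 2488 (without day 3 replicate 2), 2731 (without day 3 replicate 1), 2654 (without day 6 replicate 1) and 2574 (without day 6 replicate 2). Rescaling on reference genes moved the median of all genes from 0.015 to -0.256, that of the astrocyte list from 0.49 to 0.22, that of the committed precursor list from -0.44 to -0.72 and the share up to 19.3%.

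Against primary cells at day 3, iOPCs had higher levels of some myelin genes and lower levels of others. Mal was higher by 5.50, Cryab by 4.92, Apod by 2.74 and Mag by 1.70, while Nkx6-2 was lower (it fell by 3.48), as was Mobp (it fell by 3.18). Mbp fell by 0.44, a change not called without iOPC replicate 2 (adjusted p = 0.0569) or without day 3 replicate 2 (adjusted p = 0.0969). Olig1 was 193-fold and Omg (a myelin glycoprotein) 75.3-fold lower, and Gfap, Vxn, Fabp7, Sparcl1, Crym and Nap1l5 were 97.4-fold to 56.9-fold lower. Ccn2 was 594-fold, Col3a1 275-fold and Fn1 119-fold higher, and S100a11, Fosb, Enpp1, Pnoc and Tyrp1 were 215-fold to 117-fold higher.

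Of 33 myelin genes 12 rose and 13 fell (12 and 14 adjusted over the list alone), with a median of -0.44 and a mean of 0.08, and the list did not pass (adjusted p = 0.9). Immediate early genes had 21 rises and 0 falls (adjusted p = 3.1e-12), which held with an estimated correlation (adjusted p = 0.021). Cholesterol genes had 19 falls and 0 rises (adjusted p = 9.8e-11; adjusted p = 0.14 with an estimated correlation), among them Tm7sf2 by 3.99 and Lss by 3.10, enzymes of the sterol pathway. The fibroblast list had 31 rises and 1 fall (32 and 1 adjusted over the list alone; adjusted p = 4.3e-11, and adjusted p = 0.17 with an estimated correlation). Schwann cell genes had 16 rises and 4 falls (adjusted p = 1.8e-05; adjusted p = 0.064 with an estimated correlation). Precursor genes had 23 falls and 4 rises (25 and 4 adjusted over the list alone; adjusted p = 7e-08, and adjusted p = 0.11 with an estimated correlation). Cell cycle genes had 22 rises and 0 falls (23 and 0 adjusted over the list alone; adjusted p = 2e-05, and adjusted p = 0.43 with an estimated correlation), but 13 rises without iOPC replicate 2 and 11 without day 3 replicate 1. Hox genes had 8 rises and 1 fall (adjusted p = 0.0011; adjusted p = 0.12 with an estimated correlation), with a median of 0.21 that became -0.27 under rescaling on reference genes. For the immediate early, cholesterol, Schwann cell and Hox lists the counts adjusted over the list alone were the same.

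Committed precursor genes had 10 falls and 2 rises in iOPCs against day 3 (11 and 2 adjusted over the list alone; adjusted p = 0.0031, and adjusted p = 0.22 with an estimated correlation). Neuronal genes had 16 falls and 7 rises (the same adjusted over the list alone; adjusted p = 0.014, and adjusted p = 0.12 with an estimated correlation), Dcx by 5.06. Astrocyte genes had 11 falls and 3 rises (13 and 3 adjusted over the list alone; adjusted p = 0.0031, and adjusted p = 0.11 with an estimated correlation), Gfap by 6.61. Melanocyte genes had 5 rises and 1 fall (5 and 2 adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.21 with an estimated correlation), with Tyrp1 up by 6.87. Senescence and p53 genes had 12 rises and 1 fall (the same adjusted over the list alone; adjusted p = 0.0026, and adjusted p = 0.19 with an estimated correlation). Interferon response genes had 10 rises and 2 falls (the same adjusted over the list alone; adjusted p = 0.014, and adjusted p = 0.14 with an estimated correlation), with a median of 0.32 that became -0.16 under rescaling on reference genes.

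Of all genes 6725 changed, 3075 up and 3650 down, so 45.7% were up, and 2614 changed at least 2-fold. Rescaling on reference genes gave 10664 changed genes, moved the median of all genes from -0.032 to -0.511 and the share up to 15%, and ended the call of Myrf, which was 0.80 higher in iOPCs (adjusted p = 0.0854 when rescaled). It lowered the list medians of cell cycle genes from 0.51 to 0.03, melanocyte genes from 0.54 to 0.06, senescence genes from 0.90 to 0.42, committed precursor genes from -0.74 to -1.22, myelin genes from -0.44 to -0.92 and astrocyte genes from -0.42 to -0.90. Olig2 was higher by 1.48 on the probe set used, and the mean of its probe sets gave -0.06.

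Against primary cells at day 6, many myelin genes were lower in iOPCs. Mobp was 183-fold lower at 4.18 ± 0.26 (SD, n = 2), Opalin fell by 5.55, Ppp1r14a by 5.33 and Klk6 by 4.54, while Mog fell by 1.83 and Mbp by 1.00. Mal stood at 9.49 against 8.97, Myrf at 10.90 against 10.86 and Zfp536 at 10.44 against 10.58. Mag stood at 11.89 against 12.29, and its fall of 0.40 (adjusted p = 0.043), like that of Cnp, was not called without iOPC replicate 2 or without either day 6 array. Olig1 was 242-fold lower, and Serpinb1a, Aqp4, Gfap, Kndc1, Omg and Crym were 144-fold to 71.4-fold lower. Ccn2 was 518-fold, Col3a1 220-fold and Col1a2 101-fold higher, and S100a11, Enpp1, Fosb, Lamb1 and Gpc3 were 187-fold to 104-fold higher.

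Of 33 myelin genes 24 fell and 3 rose (adjusted p = 5.1e-06; adjusted p = 0.15 with an estimated correlation). Each of 34 cell cycle genes rose (adjusted p = 7.7e-18; adjusted p = 0.16 with an estimated correlation), Mki67 by 3.68, and each of 20 cholesterol genes fell (adjusted p = 3.5e-10; adjusted p = 0.15 with an estimated correlation). Astrocyte genes had 17 falls and 0 rises (adjusted p = 8.2e-07) and immediate early genes 20 rises and 0 falls (adjusted p = 8.5e-10), and both held with an estimated correlation (adjusted p = 0.041 and 0.036). The fibroblast list had 29 rises and 4 falls (adjusted p = 1.1e-08, and adjusted p = 0.2 with an estimated correlation). Schwann cell genes had 14 rises and 4 falls (adjusted p = 0.0003, and adjusted p = 0.077 with an estimated correlation), with Egr2, a regulator of peripheral myelin, up by 6.57. Egr2 also stands in the immediate early list, and its value was 8.43 in acutely isolated OPCs, which were panned too. Committed precursor genes had 10 falls and 2 rises (adjusted p = 0.012; adjusted p = 0.28 with an estimated correlation), but 6 falls without either day 6 array. Hox genes had 9 rises and 3 falls (adjusted p = 0.0062; adjusted p = 0.15 with an estimated correlation), with a median of 0.16 that became -0.05 under rescaling on reference genes. These counts were the same adjusted over the list alone.

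Precursor genes had 18 falls and 6 rises in iOPCs against day 6 (19 and 6 adjusted over the list alone; adjusted p = 0.0015, and adjusted p = 0.16 with an estimated correlation), Lnx1 by 5.45. Neuronal genes had 16 falls and 6 rises (16 and 7 adjusted over the list alone; adjusted p = 0.032, and adjusted p = 0.15 with an estimated correlation), Stmn3 by 3.96. Senescence and p53 genes had 10 rises and 3 falls (the same adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.23 with an estimated correlation), with Cdkn2a up by 3.89. Interferon response genes had 9 rises and 1 fall (the same adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.15 with an estimated correlation), with a median of 0.15 that became -0.06 under rescaling on reference genes. Melanocyte genes had 5 rises and 3 falls (the same adjusted over the list alone) and did not pass (adjusted p = 0.095).

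Of all genes 7207 changed, 3336 up and 3871 down, so 46.3% were up, and 2831 changed at least 2-fold. Rescaling on reference genes moved the median of all genes from -0.06 to -0.268, that of the senescence list from 0.56 to 0.35 and the share up to 29.4%.

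**Figure D3:**
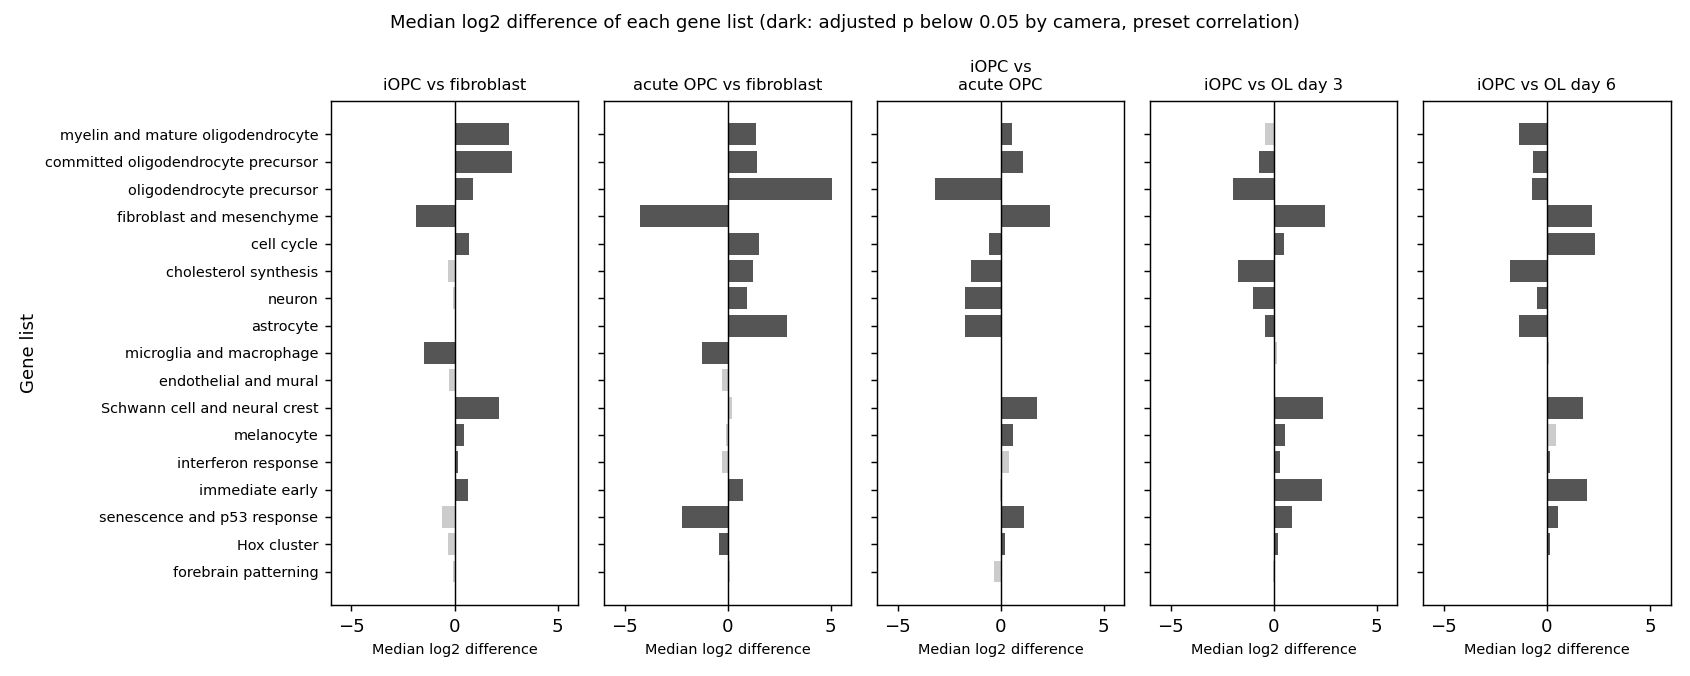
Bars give the median log2 difference (x axis) of each gene list (y axis) in 5 comparisons, dark where camera passed at the preset correlation; of all 119 list tests 7 also passed with an estimated correlation. Under rescaling on reference genes the median changed sign for the endothelial, interferon and Hox lists in every panel but the first, for the melanocyte list in the second panel and for the microglia list in the last 3 panels.

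Across all genes, iOPC arrays were most like day 3 cells, with a mean Pearson correlation of 0.899 ± 0.0043 (SD, n = 2 iOPC arrays), then day 6 cells (0.894 ± 0.0049), fibroblasts (0.872 ± 0.0055) and acutely isolated OPCs (0.841). Day 3 ranked above day 6 for each iOPC array, but over the 2000 most variable genes the order of these groups was reversed (0.456 and 0.479). Genes are not independent replicates, and no test was made. The acutely isolated OPCs were the only group lysed without culture, so their rank cannot be put down to cell identity alone.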

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

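All tests in this part were chosen after the results were seen, except the limma tests of each gene and the camera tests of the lists.

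Of 398 list and core genes, 14 changed at least 2-fold in opposite directions against the same fibroblasts in iOPCs and in acutely isolated OPCs. Of the 14, 7 fell in iOPCs and rose in OPCs, and the log2 difference of iOPCs minus OPCs was -7.05 for Slc1a3, -6.95 for Dcx, -6.68 for Nnat, -5.93 for Pdgfra, -5.78 for Cspg4, -5.52 for Celf4 and -3.58 for Lhx2. The other 7 rose in iOPCs and fell in OPCs, and the difference was 2.13 for Hoxa7, 3.37 for Eno2, 3.98 for Cd82, 4.18 for Tfap2b, 4.68 for Lpar1, 4.95 for Nefl and 6.17 for Hoxd8.

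Some fibroblast and Hox genes, such as Ccn2 and Hoxd8, stayed high in iOPCs, while others, such as Lox, fell far. Carried-over fibroblasts with the profile of the fibroblast arrays would give each abundant fibroblast gene about the same share of its fibroblast level. Over 10 such genes the 2 highest and 2 lowest shares were set aside. The highest share left was 5 times the lowest left in iOPC replicate 1 (29.4% and 5.88%). In replicate 2 it was 6.12 times the lowest left (27.1% and 4.43%). Ccn2 (48.9% and 50.3% in replicates 1 and 2) and Lox (2.54% and 0.196%) were among the shares set aside. Among 6 Hox genes the median share was 45.7% in replicate 1 and 48.7% in replicate 2, which was 7.76 and 11 times the lowest share left. A median exceeds a near-lowest share wherever shares are uneven, so these Hox ratios add little to the ratios above. Hoxd8 exceeded its fibroblast level, which no share of such fibroblasts gives. Such fibroblasts are therefore not the whole source, though fibroblasts altered by 3 weeks in other medium were not tested and compression of array values may widen the ratios. Most shares were higher in iOPC replicate 1 than in replicate 2 (Col1a2 20.5% and 8.73%, Postn 20% and 6.13%), but those of Fn1 and Ccn2 were not. Part of the signal could thus still come from such fibroblasts, in amounts that differ between the arrays. A candidate explanation that stays open is that converted cells kept part of the expression of their cells of origin.

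Schwann cell and neural crest genes were higher in iOPCs than in primary cells, though no call against a primary group held with an estimated correlation (adjusted p = 0.064 to 0.077). Some, such as Ngfr, also rose between day 3 and day 6 in primary cells, so a stage later than day 6 might account for them, but the myelin list median of iOPCs minus day 6 was -1.37 (-1.4 to -1.27 when single arrays were left out) while that of the Schwann list was 1.77. A mixture of cells on the iOPC arrays could also lower the myelin median. A later stage of only part of the cells is therefore not excluded. Crest-derived cells already present in the fibroblast cultures could be another source. Of the 20 members that rose, 13 lay below log2 5 in both fibroblast arrays, which bounds abundant cells only. Rare cells enriched by O4 panning cannot be told apart from a crest-like state of the converted cells, since no array holds infected cells that were not panned.

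Immediate early genes were higher in iOPCs and in acutely isolated OPCs than in day 3 cells. Of 23 members 18 were higher in both panned groups, a count that the pattern itself fixes and that decides nothing. Panning and cell type go together in this design, so handling during immunopanning just before lysis and a difference between the cells themselves cannot be told apart.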

How the results depend on the processing

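Of 1587 alternative values of 195 named changes, 1559 kept direction and call, 26 kept direction only and 2 reversed, both of Olig2 with the mean of all probe sets (-0.0537 for iOPCs minus OPCs, -0.0622 for iOPCs minus day 3), where its probe sets differ in direction. These named changes were the largest of each comparison and core genes already called, so selection favours their stability. It does not extend to all genes. List counts also rest on 1 probe set per gene. Over the comparisons, 757 calls of list or named genes were of genes with several probe sets. Among these, 322 had a probe set that was not called and 15 had a probe set called the other way. Ncam1 of the Schwann cell list was among the 15, and its probe sets ranged from -0.88 to 1.78 in iOPCs against fibroblasts. Over all genes, leaving out single arrays ended a larger part of the calls, though no called gene changed direction. Of 598 alternative list counts, 546 stayed within 1.5 times. The 2-fold minimum, by construction, lowered the numbers of changed genes to 2990 (iOPC and fibroblast), 4597 (OPC and fibroblast), 3598 (iOPC and OPC), 2794 (day 3 and OPC), 1298 (day 6 and day 3), 2614 (iOPC and day 3) and 2831 (iOPC and day 6), and shared calls to 1903. Rescaling on reference genes gave 10664 for iOPC and day 3. It shifts all genes of an array by the same amount, and here the median of all genes moved from -0.032 to -0.511. Falls thus went from 3650 to 9064 and rises from 3075 to 1600. Why the reference genes differed between these groups was not tested. For day 6 and day 3, the fit of only those groups gave 7005 (cause not tested), and leaving out single arrays 2488 to 2731, with fewer samples. Fits with a block for the replicate number gave 7016, 4434, 6596 and 7037 for the comparisons among numbered arrays, all within 1.5 times. Similarity of iOPCs to OPCs was 0.8407 after quantile normalisation, 0.8439 with the mean of probe sets and 0.843 by Spearman. With dim genes left out it was 0.7822 (fibroblasts), 0.7242 (OPCs), 0.8265 (day 3) and 0.8219 (day 6), and with the 2000 most variable genes 0.3845, 0.2171, 0.4558 and 0.4793. The cause of these shifts was not tested. Fits of only 2 groups for list counts, and left-out arrays for the lists other than myelin, precursor and fibroblast, were added after the data were seen. Array background limits what can be said of dim genes.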

Other observations

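The genes in this part were chosen after their values were seen.

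Some genes set the iOPCs apart from every other group. In limma's tests 634 genes were higher in iOPCs than in each of the other 4 groups, 71 of them at least 4-fold in each, and 464 were lower, 18 of them at least 4-fold. Pnoc (the nociceptin precursor) stood at 11.48 in iOPCs, at least 64-fold above each other group, and Npy (neuropeptide Y) at 12.77, at least 47.9-fold. Scn7a stood at 10.23, Lama2 (a laminin chain) at 8.85, Cdh1 (E-cadherin) at 8.03 and Dhh (desert hedgehog, a signal made by Schwann cells) at 9.20. Lowest relative to the others were Rcan2 (4.25, 15.5-fold below the nearest group), Rnf180 (3.95), Dcx (doublecortin, 3.38), Slc1a3 (a glial glutamate transporter, 4.54) and S1pr1 (4.68).

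Eif2s3y, a gene of the Y chromosome, stood at 3.21 in the acutely isolated OPCs and at 8.20 to 8.47 in the other groups, while Uty, also of the Y chromosome, stood at 8.59 in the OPCs and at 8.45 to 8.81 in the others on the probe set used. Its other probe set lay at 3.56 to 3.99 in every group, and whether the first is specific to the Y chromosome was not tested. The Xist value was 11.10 in the OPCs, 10.21 in iOPCs, 7.66 in fibroblasts, 8.70 at day 3 and 8.36 at day 6. The sex of the animals was not inferred.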
